A study of Mus musculus with 19 samples.

How the data were processed

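Gene expression was measured by RNA sequencing of total RNA, extracted with the RNeasy Micro Kit per the labels' protocols, in 6 samples of cultured LL/2 cells and 13 LL/2 tumours. The authors deposited 1 table of whole-number read counts per Ensembl gene for all 19 libraries, not scaled to depth. Per the submitters' processing notes, cutadapt, FastQC, HISAT2 and StringTie were used with genome build mm10. Their versions, the annotation release, the strand setting and how counts were written out by StringTie were not given in the sources used here. Because the strand setting is unknown, reads of overlapping or antisense genes may be assigned to either partner, and genes of families with near-identical copies (Gbp, H2, Gzm, Hba, Hbb, Hspa1a and Hspa1b) are uncertain.

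The table held 55401 rows, of which 55141 matched a gene of GENCODE M21 (GRCm38, the assembly named mm10) by Ensembl identifier, which gave symbols and coordinates, and 260 did not match. Coordinates are 1-based. Where a symbol had several rows, the one with the highest mean stood for it.

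Each library's group was taken from its treatment label, and the 3 shNTRK libraries were treated as 1 group by their titles. Their treatment labels end in 1, 2 and 3 as their titles do, and these could mark replicates, hairpins or genes, so no difference between them was tested. Nothing in the labels says whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical in part. No batch, date, host sex or tumour site was given in the labels. The replicates were compared by a chi-square test of their counts in each gene with a summed count of at least 100. The median per pair was 4.314 to 30.15 over the 21 pairs within groups, so no 2 libraries agreed within sampling noise and all were kept as separate replicates.

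The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, the default expression filter (16577 genes kept in cells, 19983 in tumours) and Benjamini-Hochberg adjustment at 0.05. The 6 cell libraries were fitted together, and the 13 tumours of the 4 treatments were fitted together so that they share 1 estimate of the spread. The interaction was the contrast of combination minus entrectinib minus anti-PD1 plus IgG. CPM values use TMM effective library sizes. The SE of a log2 fold change is its size divided by the square root of the F statistic.

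Gene lists of pathways, cell types and quality marks, 45 in all, were fixed together with the tests and the alternatives before the data were examined. Each was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, then with an estimated correlation and with fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes. Lists share members, for example Psmb9 and Tap1 in the interferon gamma and MHC class I lists. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes to be named were, first, the treatments' targets and genes related to them, such as Ngf and Cd274. Next were up to 8 highest and 8 lowest folds among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. Last were up to 4 members with the smallest p of each list that had a call or several members past the threshold. Where fewer than 5 genes met the rule for folds, the 5 with the smallest p are given as values. Atf4, Asns, Psat1, Creld2, Pdia4, Sdf2l1 and Vegfa in the cells, the values of Acta1, Cd8a and Cd274 per library, the Y-linked genes, Xist, Krt5, Meg3 and Fn1 and Ltf per library were named after their values were seen.

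Alternatives were RLE scaling, no expression filter, a stricter filter (1 CPM in at least 3 libraries and a summed count of at least 100), limma-voom, DESeq2 1.42.0, the replicate number as a block, summing by symbol, fitting only the groups compared, and leaving out each replicate. Scaling by total counts without TMM, and combination replicates 1 and 2 only or 3 and 4 only, were added after seeing the data. The test was run on simulated counts with changed genes of known fold. In the cells (16577 genes simulated) it recovered 9%, 26.9% and 69.7% of genes changed 1.5-fold, 2-fold and 4-fold, in combination against anti-PD1 (19983 genes) 23.9%, 44.8% and 68.2%, and in the interaction 4.5%, 31.3% and 60.6%. Each fold was given to 66 or 67 genes, far fewer than the 7141 that passed in the real cells. The adjustment is stricter with so few changed genes, so the rates do not give the recovery in the real cell comparison. A gene at 0 in a group was given a limit of 3 counts over the group. Such limits cover counting error only.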

Results

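RNA sequencing was used to measure gene expression in 19 samples of LL/2, a mouse Lewis lung carcinoma line. Of these, 6 were cell line samples, 3 labelled with a control hairpin (shCTRL) and 3 labelled shNTRK, from what the series describes as a knockdown of NTRK1. Ntrk1 encodes TrkA, the receptor for nerve growth factor. The other 13 were tumours from mice given control IgG (3 tumours), entrectinib (3), an antibody against PD-1 (3) or entrectinib together with anti-PD1 (4, called the combination here). Entrectinib is an oral inhibitor of the TRK, ROS1 and ALK kinases, and PD-1 is an inhibitory receptor of T cells. The stated interest was in how NTRK1 bears on the response to checkpoint inhibition in lung cancer. Total counts per library were 75956897 to 76338524 in the IgG tumours, 75417565 to 77944087 with entrectinib, 63091730 to 78140310 with anti-PD1, and 75999437, 77519488, 53395410 and 56004042 in combination replicates 1 to 4. They were 59990935 to 74602716 in shCTRL and 58662542 to 62723733 in shNTRK cells. Values are depth-scaled counts (CPM), given as mean ± SD over the replicates. Log2 fold changes are given as estimate ± SE.

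The targeted gene was almost absent from every library. Ntrk1 (ENSMUSG00000028072, chromosome 3, 87778244 to 87795162, GRCm38) had 0 counts in each of the 3 shCTRL and each of the 3 shNTRK libraries, so the knockdown could not be measured at this depth and the hairpin labels could not be checked by their target. A count of 0 over a group allowed up to 0.01443 CPM in shCTRL and 0.01665 CPM in shNTRK cells, and these limits cover counting error only. In the tumours Ntrk1 had 16, 0 and 8 counts with IgG, 0, 0 and 8 with entrectinib, 0, 9 and 0 with anti-PD1, and 12, 0, 2 and 0 with the combination. Cd274, which encodes the PD-1 ligand PD-L1, was at 31.5 ± 11.8 CPM in IgG tumours, 26.1 ± 7.49 with entrectinib, 31.2 ± 4.03 with anti-PD1 and 82.9 ± 30.7 with the combination. Pdcd1, which encodes PD-1, was at 1.42 ± 0.653, 1.51 ± 0.688, 2.8 ± 0.787 and 7.09 ± 2.27 CPM in the same order.

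The cell line comparison asked how expression differed between LL/2 cells labelled shNTRK and cells with the control hairpin. Many inflammatory, stress and sterol genes rose in the shNTRK cells. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose from 0.930 ± 0.179 CPM in shCTRL to 132.4 ± 45.8 CPM in shNTRK cells (n = 3 each), a log2 fold change of 7.16 ± 0.35 (adjusted p = 2.813e-05). Cxcl1, a chemokine that draws neutrophils (chromosome 5, 90891241 to 90893115), rose from 5.38 ± 0.847 to 191.4 ± 14.9 CPM (log2 5.15 ± 0.17, adjusted p = 1.844e-05). The cholesterol synthesis gene Hmgcs1 (chromosome 13, 119690379 to 119708260) rose from 41.1 ± 9.04 to 371.1 ± 9.84 CPM, and the endoplasmic reticulum chaperone gene Hspa5 (chromosome 2, 34771970 to 34777547) from 1075 ± 42.1 to 5926 ± 290.4 CPM. In the other direction, Slc7a11, the cystine transporter (chromosome 3, 49892526 to 50443614), fell from 96.8 ± 37.4 to 5.53 ± 0.561 CPM, and Trib3, a target of the stress factor ATF4, from 361.8 ± 54.8 to 36.8 ± 8.41 CPM.

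Members of several inflammatory lists rose. Of 20 measured TNF and NF-kB targets, 12 rose and 0 fell over all genes tested, and 14 rose adjusted over the list alone (median log2 0.73, camera adjusted p = 1.305e-11, adjusted p = 0.09909 with an estimated correlation). Among them Tnfaip3, which restrains NF-kB, went from 4.86 ± 1.34 to 89.1 ± 12.4 CPM, and Nfkbia, the NF-kB inhibitor, from 21.4 ± 1.68 to 205.7 ± 6.86 CPM. Chemokine genes rose in 10 of 15 members with 0 lower, and in 10 adjusted over the list alone. The median was 1.93 (camera adjusted p = 3.93e-09, adjusted p = 0.14 with an estimated correlation). Ccl2, which attracts monocytes, rose from 9.47 ± 0.410 to 106.3 ± 15.2 CPM, and Cxcl10, induced by interferon, had a log2 change of 4.56. For MHC class I antigen presentation, 13 of 20 genes rose and 2 fell by either adjustment, over all genes or adjusted over the list alone. The median was 0.99 (camera adjusted p = 2.644e-05, adjusted p = 0.4876 with an estimated correlation). Its members include B2m, the light chain of class I molecules (157.9 ± 16.6 to 625.5 ± 96.7 CPM), and the peptide-loading chaperone Calr (272.2 ± 21.5 to 1457 ± 173.1 CPM). The interferon gamma response list had 9 of 22 genes higher and 3 lower, the same 9 and 3 adjusted over the list alone. The median was 0.75 (camera adjusted p = 0.03138, adjusted p = 0.3917 with an estimated correlation). Cd274 itself had a log2 change of 0.09 (adjusted p = 0.7177), which turned to -0.08 when libraries were scaled by total counts without TMM.

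Immediate early and stress genes, a list fixed beforehand as a mark of quality, also had high folds. Of 18 measured, 14 rose and 1 fell, by adjustment over all genes and adjusted over the list alone. The median was 2.19 (camera adjusted p = 7.247e-15, adjusted p = 0.3376 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, rose from 0.857 ± 0.464 to 39.0 ± 12.4 CPM, Egr1, an early growth response factor, from 8.46 ± 1.62 to 252.1 ± 96.7 CPM, and Hspa1a, an inducible heat shock protein gene with the near-identical copy Hspa1b, from 1.30 ± 0.0352 to 173.7 ± 71 CPM. Sterol genes rose almost throughout. In cholesterol synthesis 19 of 20 genes rose and 0 fell, and 19 adjusted over the list alone (median 2.13, camera adjusted p = 4.968e-28, adjusted p = 0.1238 with an estimated correlation), among them Idi1, an isoprenoid isomerase (13.2 ± 2.11 to 128 ± 13.2 CPM), and Hmgcr, the rate-limiting reductase (48.5 ± 5.89 to 230 ± 23.6 CPM). Soat2, which esterifies cholesterol, fell from 27.9 ± 5.10 to 0.585 ± 0.281 CPM. The libraries differed in other marks of quality as well. The 10 most abundant genes took 10.04 to 10.93% of the counts in shNTRK and 7.01 to 8.03% in shCTRL libraries. Of the 13 mitochondrially encoded genes, 10 fell and 1 rose, with 10 and 1 adjusted over the list alone (median log2 -1.11, camera adjusted p = 5.019e-07, adjusted p = 0.4866 with an estimated correlation), while the share of counts from the mitochondrial chromosome was 3.42 to 3.916% in shNTRK and 3.566 to 4.388% in shCTRL libraries. Ribosomal protein genes rose in 22 of 24, and in 23 adjusted over the list alone (median 0.63, camera adjusted p = 0.0002902, adjusted p = 0.6966 with an estimated correlation), and in 10 of 24 with total-count scaling without TMM.

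The list of ATF4 and unfolded protein response genes had members that went both ways. Of its 20 genes 6 rose and 10 fell, and 6 rose and 11 fell adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.7511). Those that rose include the chaperones and folding enzymes Hspa5, Hsp90b1 (log2 1.28), Pdia4 (1.15), Creld2 (1.83) and Sdf2l1 (1.61), and those that fell include asparagine synthetase Asns (-1.75), the serine pathway gene Psat1 (-0.74) and Slc7a11 (-4.13 ± 0.29). These genes were grouped after their values were seen, and no test compared the groups. Atf4 itself had a log2 change of -0.86 ± 0.17 (adjusted p = 0.005364). Hypoxia response genes rose in 14 of 19 and fell in 3, with 14 and 4 adjusted over the list alone. The median was 1.23 (camera adjusted p = 1.415e-06, adjusted p = 0.4876 with an estimated correlation). Adm, which encodes the vasodilator adrenomedullin, rose from 8.42 ± 2.00 to 123.2 ± 23.7 CPM, whereas Vegfa had a log2 change of 0.43. Glycolysis genes rose in 11 of 16 and fell in 2, with 11 and 3 adjusted over the list alone (median 0.63, camera adjusted p = 0.01282, adjusted p = 0.4876 with an estimated correlation), for example Pgk1 (log2 1.07) and Gpi1 (1.1). For p53 targets 9 of 19 rose and 2 fell, with 11 and 2 adjusted over the list alone (median 0.41, camera adjusted p = 2.788e-05, adjusted p = 0.2848 with an estimated correlation), led by the death receptor gene Fas (4.09) and by Plk2 (3.32). TGF-beta targets rose in 9 of 19 and fell in 4, with 9 and 4 adjusted over the list alone, and the camera call (adjusted p = 0.002238) had an adjusted p = 0.2083 with an estimated correlation. Serpine1, the plasminogen activator inhibitor, was among those that rose (2.76). Snai2, which belongs to the epithelial and mesenchymal list and not to this one, fell (-2.2). Ngf, the ligand of TrkA, rose from 7.39 ± 1.61 to 14.9 ± 3.67 CPM (adjusted p = 0.009486).

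**Figure D1:**
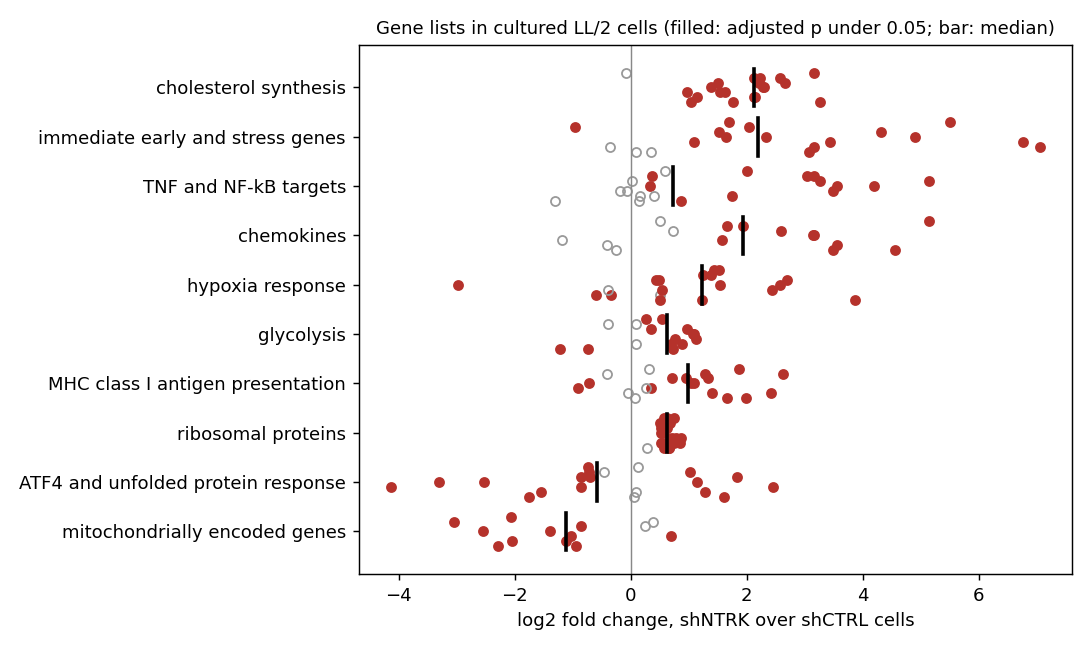
Log2 fold change of each member of 10 gene lists between shNTRK and shCTRL cells (n = 3 each), with filled points for genes with an adjusted p under 0.05 and a bar at the list's median. The cholesterol synthesis list has its median at 2.13 and the mitochondrially encoded list at -1.11.

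By edgeR's quasi-likelihood test, 7141 of 16577 genes differed between shNTRK and shCTRL cells at an adjusted p under 0.05, 3333 higher and 3808 lower, and 1449 of the higher and 2098 of the lower changed more than 2-fold. The replicates of the groups did not overlap for 56.1% of the genes tested, where chance gives 10% for 3 against 3. With total-count scaling without TMM the median of all genes moved from -0.02 to -0.19, and 34.1% of 7277 genes were higher against 46.7% with TMM. The balance of directions turned when a trend was removed from each library, to 4371 higher and 3620 lower with transcript length and 3916 higher and 3517 lower with GC content, so which direction is the more frequent stays open. No list kept its camera call with an estimated correlation in this comparison.

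The tumours were compared to ask how entrectinib and anti-PD1, alone and together, changed expression. On the first principal component, which held 28.6% of the variance, the combination tumours of replicates 3 and 4 lay at -116 and -112.9, and the other 11 tumours between -22 and 49.4. The second, with 11.9%, placed combination replicates 1 and 2 at -66.4 and -61.2. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 0.1248 to 0.517 CPM in combination replicates 3 and 4 and at 1.987 to 13.97 CPM in each of the other 11 tumours. No IgG, entrectinib or anti-PD1 tumour had such low values. Every comparison with all 4 combination tumours, and the interaction, thus mixes treatment with whatever set replicates 3 and 4 apart. Skeletal muscle RNA also varied. Acta1, skeletal muscle actin (chromosome 8, 123891769 to 123894751), was at 36.1 to 72.8 CPM in the IgG tumours, at 0.1731 to 0.6443 CPM in the 4 combination tumours, and at 0.4235 and 0.5065 CPM in entrectinib replicate 2 and anti-PD1 replicate 2, whose partners were at 33.4 to 42.8 CPM.

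**Figure D2:**
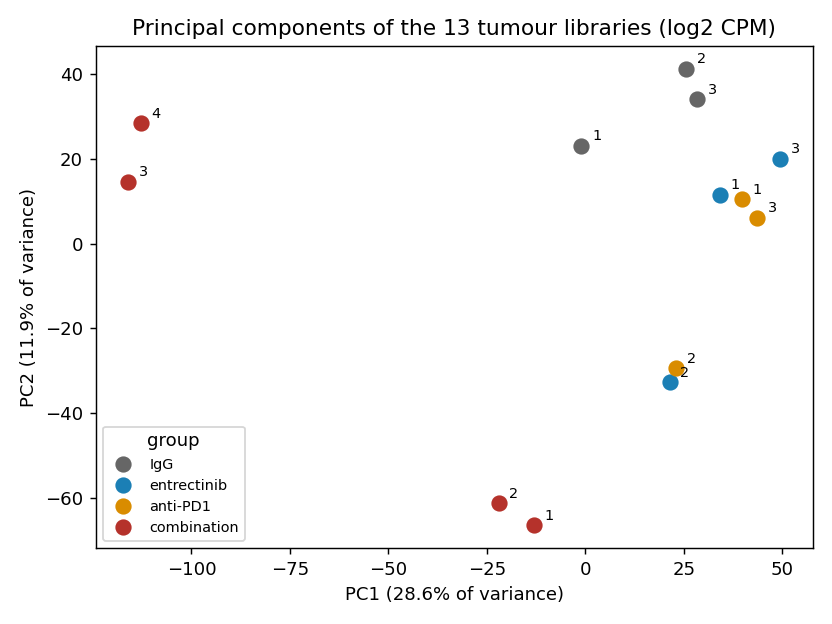
First and second principal components (28.6% and 11.9% of the variance) of log2 CPM in the 13 tumours, with each point a tumour, the colour its treatment and the number its replicate. Combination replicates 3 and 4 lie apart on the first component, at -116 and -112.9.

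Entrectinib alone was compared with IgG, with 3 tumours each, and no single gene passed the test. Irf7, a regulator of type I interferon genes, was at 18.9 ± 3.42 CPM with entrectinib and 36.0 ± 11.4 CPM with IgG, and the antiviral gene Oas1a at 15.3 ± 2.56 and 24.9 ± 3.85 CPM. Over the 28 interferon alpha response genes the median log2 change was -0.62 with 0 genes past the threshold over all genes and 10 lower adjusted over the list alone (camera adjusted p = 3.726e-20, adjusted p = 0.6384 with an estimated correlation). The 7 measured erythroid genes had a median of -1.57, with 0 past the threshold over all genes and 5 lower adjusted over the list alone (camera adjusted p = 9.297e-07, adjusted p = 0.5733 with an estimated correlation). The beta-globin gene Hbb-bs, a member of a multigene family, was at 44.8 ± 12.3 CPM with entrectinib against 187.3 ± 152.2 CPM. The alpha-globin gene Hba-a1 was at 135.5, 52.9 and 39.4 CPM in IgG replicates 1 to 3 and at 8.976 to 35.05 CPM in the other tumours. Immediate early and stress genes had a median of 0.42 and 3 members higher adjusted over the list alone (camera adjusted p = 9.297e-07, adjusted p = 0.6384 with an estimated correlation), for example Ier2 at 48.7 ± 4.06 and 33.9 ± 2.43 CPM. Camera also called p53 targets lower, with a median of -0.28 and 1 gene higher and 1 lower adjusted over the list alone (adjusted p = 0.0002574, and adjusted p = 0.6384 with an estimated correlation). So it did, with 0 genes adjusted over the list alone in each, for cholesterol synthesis (median -0.14, adjusted p = 0.001024, and adjusted p = 0.6645 with an estimated correlation), keratinocyte and hair genes (-4.62, 0.001542, and adjusted p = 0.6741 with an estimated correlation) and ATF4 and unfolded protein response genes (-0.23, 0.001659, and adjusted p = 0.6645 with an estimated correlation). Among the IgG and entrectinib tumours the keratin gene Krt5 stood out in IgG replicate 2 alone. The keratinocyte call may thus rest on that tumour, which was not tested. Collagens and matrix (-0.28, 0.003492, and adjusted p = 0.7179 with an estimated correlation) and skeletal muscle genes (-0.39, 0.01112, and adjusted p = 0.9513 with an estimated correlation) were called lower too, with 0 genes adjusted over the list alone. So were TNF and NF-kB targets (-0.13, 0.01178) and JAK and STAT signalling (-0.11, 0.03901). Called higher were MHC class II (0.2, 0.03901), alternatively activated macrophage genes (0.24, 0.03986) and ribosomal proteins (0.1, 0.03901). Each of these lists had 0 genes adjusted over the list alone and an adjusted p of 0.6645 to 0.9919 with an estimated correlation.

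The genes with the smallest p were Qpct, a glutaminyl cyclase (7.11 ± 1.005 and 3.80 ± 0.700 CPM, log2 0.9 ± 0.18), Fads2, a fatty acid desaturase (65.9 ± 4.70 and 98.9 ± 4.18 CPM, log2 -0.59 ± 0.12), Pmaip1 (log2 0.84), Ppp3ca (0.47) and Tns1 (0.66), each with an adjusted p of 0.6247. With edgeR, 0 of 19983 genes passed. An unadjusted p under 0.05 was seen for 1168 genes, little more than the share of 0.05 that chance gives. DESeq2 called 36 genes and limma-voom 0. The test called 3 genes without IgG replicate 1 and 1 gene without entrectinib replicate 2. Simulated genes at this design were recovered in 17.9%, 41.8% and 65.2% of cases for 1.5-fold, 2-fold and 4-fold changes.

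Anti-PD1 alone against IgG, again with 3 tumours each, likewise gave no gene past the threshold, and several immune lists, though not all, had medians above 0. Stat1, the transcription factor downstream of interferons, was at 147.6 ± 11.3 CPM with anti-PD1 and 106.3 ± 29.1 CPM with IgG, and Ifngr2, a subunit of the interferon gamma receptor, at 62.4 and 47.6 CPM. The 25 interferon gamma response genes had a median log2 change of 0.25, with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 9.86e-08, adjusted p = 0.7595 with an estimated correlation). For neutrophil markers the median was 0.48 over 16 genes (camera adjusted p = 1.912e-05, adjusted p = 0.7595 with an estimated correlation), for CD8 T and NK cytotoxicity genes 0.36 over 17 (0.0007578, adjusted p = 0.7595 with an estimated correlation) and for T cell markers 0.37 over 14 (0.004369, adjusted p = 0.852 with an estimated correlation), with 0 members past the threshold in each by either adjustment, adjusted over the list alone included. Ltf, a neutrophil granule protein, was at 8.59 ± 2.76 and 0.683 ± 1.02 CPM. The erythroid list had a median of -1.4 and 5 of 7 genes lower adjusted over the list alone (camera adjusted p = 3.159e-06, adjusted p = 0.3884 with an estimated correlation). Interferon alpha response genes had a median of -0.2 (camera adjusted p = 0.06095), B and plasma cell markers -0.1 (0.575), dendritic cell markers -0.07 (0.3271) and regulatory T cell markers 0.02 (0.8082). Skeletal muscle genes had a median of -0.48 (camera adjusted p = 0.0004487, adjusted p = 0.7595 with an estimated correlation) and cholesterol synthesis genes -0.14 (0.0005442, adjusted p = 0.7595 with an estimated correlation), with 0 genes in each adjusted over the list alone. Acta1 was at 40.46, 0.5065 and 33.41 CPM in anti-PD1 replicates 1 to 3.

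The smallest p belonged to Rad54b, a DNA repair helicase (12.1 ± 1.28 CPM with anti-PD1 and 17.7 ± 0.927 CPM with IgG), Ptk2b, a relative of focal adhesion kinase (51.9 ± 3.33 and 39.5 ± 1.51 CPM), Adcyap1r1 (log2 -0.7), Rab32 (0.54) and Il10rb (0.33), each with an adjusted p of 0.9965. With edgeR 0 of 19983 genes passed. An unadjusted p under 0.05 was seen for 786 genes, fewer than the share of 0.05 that chance gives. DESeq2 called 8 genes, limma-voom 0, and edgeR without IgG replicate 1 called 1.

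The combination was compared with IgG (4 tumours against 3), and members of the interferon gamma, antigen presentation and T cell lists rose. Stat1 (chromosome 1, 52119440 to 52161865) rose from 106.3 ± 29.1 CPM in IgG to 385.7 ± 53.2 CPM in combination tumours (log2 1.86 ± 0.18, adjusted p = 0.0004428). Cxcl9, an interferon gamma-induced chemokine that draws T cells (chromosome 5, 92321347 to 92328079), rose from 88.7 ± 33.3 to 349.7 ± 11.7 CPM (log2 1.98 ± 0.26, adjusted p = 0.001442). Gzmb, the granzyme B of cytotoxic lymphocytes (chromosome 14, 56258838 to 56262260), rose from 10.5 ± 4.06 to 40.7 ± 5.42 CPM (log2 1.95 ± 0.27, adjusted p = 0.00185), and Cd274 from 31.5 ± 11.8 to 82.9 ± 30.7 CPM (log2 1.4 ± 0.3, adjusted p = 0.0209). Cd274 was at 57.3, 58.92, 121.2 and 94.33 CPM in combination replicates 1 to 4 and at 24.24 to 45.18 CPM with IgG. Members of the skeletal muscle and sterol lists fell.

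All 25 interferon gamma response genes rose, over all genes and adjusted over the list alone (median 1.67, camera adjusted p = 9.662e-76), and this call held with an estimated correlation (adjusted p = 0.02788). Ifi47, an immunity-related GTPase gene (chromosome 11, 49076587 to 49096974), rose from 52.8 ± 13.4 to 164 ± 12.03 CPM, Irf1, a transcription factor of the response, from 169.7 ± 11.2 to 338.4 ± 20.3 CPM, and Gbp2, a guanylate-binding protein of a multigene family, from 200.6 ± 66.4 to 872.9 ± 145.8 CPM. In MHC class I antigen presentation 14 of 20 genes rose, and 18 adjusted over the list alone (median 0.74, camera adjusted p = 1.206e-32), which held as well (adjusted p = 0.02788 with an estimated correlation). The immunoproteasome gene Psmb9 rose from 18.8 ± 4.30 to 52.5 ± 8.66 CPM. MHC class II genes rose in 9 of 12, and in 10 adjusted over the list alone (median 1.51, camera adjusted p = 2.937e-19, adjusted p = 0.0603 with an estimated correlation), among them H2-DMb1, which loads peptides (28.9 ± 4.05 to 83.4 ± 8.31 CPM), and the invariant chain Cd74 (193.7 ± 66.5 to 734 ± 136.1 CPM). The interferon alpha response list had 5 of 28 genes higher and 11 adjusted over the list alone. The median was 0.57 (camera adjusted p = 8.426e-13, adjusted p = 0.2601 with an estimated correlation).

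For CD8 T and NK cytotoxicity 11 of 17 genes were called higher, and 15 adjusted over the list alone (median 2.09, camera adjusted p = 7.508e-21, adjusted p = 0.0603 with an estimated correlation), and perforin, Prf1, went from 3.55 ± 1.78 to 18.04 ± 5.48 CPM. T cell markers were higher in 6 of 14, and in 14 adjusted over the list alone (median 1.74, camera adjusted p = 3.394e-13, adjusted p = 0.1356 with an estimated correlation), such as the T cell receptor subunits Cd3d (log2 2.22) and Cd3g (2.23). B and plasma cell markers had 0 of 14 genes higher by either adjustment (median -0.1, camera adjusted p = 0.9203). Checkpoint and exhaustion genes followed, with 7 of 13 higher and 10 adjusted over the list alone. The median was 1.15 (camera adjusted p = 4.75e-09, adjusted p = 0.0603 with an estimated correlation). Pdcd1 rose by a log2 change of 2.32 ± 0.4 (adjusted p = 0.008267), Lag3 by 1.97 and Ctla4 by 1.96. Macrophage markers were higher in 8 of 18, and adjusted over the list alone in 11 with 1 lower. The median was 0.55 (camera adjusted p = 7.749e-10, adjusted p = 0.1356 with an estimated correlation). Complement genes were higher in 8 of 21, and 15 adjusted over the list alone (median 0.8, camera adjusted p = 5.56e-10, adjusted p = 0.0603 with an estimated correlation), including C3 (1.54) and Cfb (1.59). Retnla, a macrophage and epithelial gene, had a high fold (log2 6.53 ± 1.3) with values of 15.57, 1.299, 25.33 and 8.967 CPM in the 4 combination tumours against a mean of 0.137 CPM with IgG.

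Among genes that fell were Fn1, fibronectin (3169 ± 654.8 to 1254 ± 221.5 CPM), and the matrix proteoglycan gene Lum (444.2 ± 175.4 to 105.6 ± 37.9 CPM), while the fibroblast list as a whole had 2 of 14 genes higher and 3 lower, and 5 and 4 adjusted over the list alone. Of the collagens and matrix list 0 of 18 genes were higher and 4 lower, and 5 lower adjusted over the list alone (median -0.12, camera adjusted p = 0.019, adjusted p = 0.5801 with an estimated correlation). Cholesterol synthesis genes were lower in 8 of 21, and in 15 adjusted over the list alone (median -0.46, camera adjusted p = 2.344e-14, adjusted p = 0.05097 with an estimated correlation), for example Idi1 (124.8 ± 3.63 to 78.3 ± 6.19 CPM). Skeletal muscle genes were lower in 10 of 20, and in 14 adjusted over the list alone (median -3.98, the same with the 3 genes at 0 in the combination set to their bound, camera adjusted p = 2.481e-15, adjusted p = 0.1063 with an estimated correlation). Acta1 fell from 52.9 ± 18.6 to 0.397 ± 0.203 CPM, and creatine kinase Ckm (chromosome 7, 19404776 to 19422841), at 14.3 ± 4.17 CPM with IgG, was at least 1251-fold lower, with 0 counts in the 4 combination tumours against a limit of 3 counts over the group. Erythroid genes were lower in 5 of 7, and 5 adjusted over the list alone. The median was -1.98 (camera adjusted p = 2.514e-08, adjusted p = 0.0603 with an estimated correlation).

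**Figure D3:**
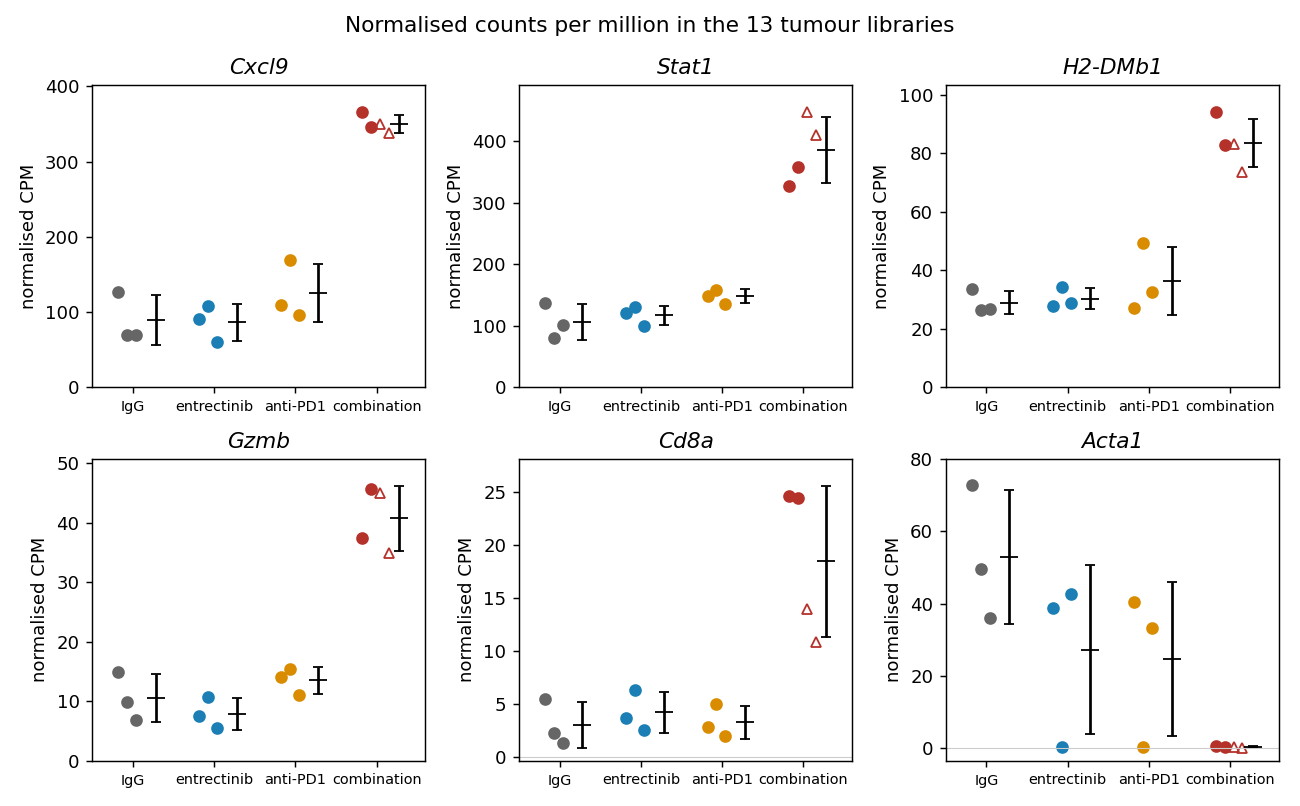
CPM per library of Cxcl9, Stat1, H2-DMb1, Gzmb, Cd8a and Acta1 in the 13 tumours by treatment, with bars for mean and SD and open triangles for combination replicates 3 and 4. Gzmb lies at 34.9 to 45.7 CPM in the combination tumours and at 5.45 to 15.5 CPM in the others.

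By edgeR, 770 of 19983 genes differed between combination and IgG tumours, 483 higher and 287 lower, 272 and 108 of them by more than 2-fold, and 3983 had an unadjusted p under 0.05. With combination replicates 1 and 2 only, an alternative chosen after seeing the data, 360 genes passed, 275 higher and 85 lower, and 275 of the 360 were among the 770. In that fit 18 of the 25 interferon gamma genes passed (median 1.44, adjusted p = 0.08504 with an estimated correlation), 8 cytotoxicity genes (median 2.33), 9 T cell markers (2.26), 4 cholesterol genes and 0 muscle genes, though the muscle median was -4.56. With replicates 3 and 4 only, also chosen after seeing the data, 2262 passed (1183 higher, 1079 lower), and DESeq2 called 1861. The count was 170 without IgG replicate 2, 138 without IgG replicate 3 and 337 without combination replicate 3.

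The combination was next compared with anti-PD1 alone, to ask what entrectinib added to the antibody. The answer is mixed with whatever set combination replicates 3 and 4 apart. Interferon genes again stood out. Gbp4 rose from 57.0 ± 14.5 CPM with anti-PD1 to 262.6 ± 74.3 CPM with the combination, Cxcl9 from 125.2 ± 39.1 to 349.7 ± 11.7 CPM (log2 1.48 ± 0.26, adjusted p = 0.01253) and Stat1 from 147.6 ± 11.3 to 385.7 ± 53.2 CPM (log2 1.39 ± 0.17, adjusted p = 0.003272). Cd8a, the coreceptor of cytotoxic T cells (chromosome 6, 71373427 to 71379173), rose from 3.33 ± 1.56 to 18.5 ± 7.12 CPM (adjusted p = 0.02461), with 24.64, 24.5, 14.03 and 10.85 CPM in the 4 combination tumours. Ifng, interferon gamma itself, rose from 0.750 ± 0.268 to 4.18 ± 2.02 CPM (adjusted p = 0.03651), Gzmb from 13.5 ± 2.30 to 40.7 ± 5.42 CPM, and Cd274 by a log2 change of 1.41 ± 0.3 (adjusted p = 0.02747). Pdcd1 had a log2 change of 1.34 (adjusted p = 0.06429) and did not pass.

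Interferon gamma response genes rose in 21 of 25, and in 25 adjusted over the list alone (median 1.42, camera adjusted p = 8.271e-48, adjusted p = 0.1436 with an estimated correlation), and interferon alpha response genes in 6 of 28, with 26 adjusted over the list alone. The median was 0.81 (camera adjusted p = 2.751e-16, adjusted p = 0.3261 with an estimated correlation). Antigen presentation showed 13 of 20 class I genes higher, 17 adjusted over the list alone (median 0.61, camera adjusted p = 7.56e-20, adjusted p = 0.1436 with an estimated correlation), and 7 of 12 class II genes, 9 adjusted over the list alone. The median was 1.09 (camera adjusted p = 6.159e-11, adjusted p = 0.2946 with an estimated correlation). H2-DMb1 rose from 36.3 ± 11.6 to 83.4 ± 8.31 CPM. For cytotoxicity genes 7 of 17 were higher, and 15 adjusted over the list alone (median 1.59, camera adjusted p = 1.003e-12, adjusted p = 0.2946 with an estimated correlation), for T cell markers 1 of 14 and 13 adjusted over the list alone. The median was 1.44 (camera adjusted p = 1.65e-07, adjusted p = 0.4434 with an estimated correlation). Lower genes included Osr2, a mesenchymal transcription factor (34.7 ± 3.68 to 7.45 ± 2.10 CPM, adjusted p = 0.002274), the cysteine protease gene Ctsk (log2 -1.62) and the matrix metalloprotease gene Mmp9 (-1.45). Muscle genes were lower in 7 of 20, and in 13 adjusted over the list alone (median -3.24, camera adjusted p = 1.046e-07, adjusted p = 0.4422 with an estimated correlation), and Acta1 was at 40.46, 0.5065 and 33.41 CPM in the anti-PD1 tumours. Cholesterol synthesis genes were lower in 3 of 21, and in 8 adjusted over the list alone. The median was -0.27 (camera adjusted p = 1.107e-06, adjusted p = 0.2946 with an estimated correlation).

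The test called 769 of 19983 genes between combination and anti-PD1 tumours, 422 higher and 347 lower, with 4864 at an unadjusted p under 0.05. With combination replicates 1 and 2 only, chosen after seeing the data, 63 genes passed (50 higher, 13 lower, 55 shared with the 769), among them 8 interferon gamma genes, 3 class I genes and 1 cytotoxicity gene. Replicates 3 and 4 only, chosen likewise, gave 3588 (1747 higher, 1841 lower), and DESeq2 called 2484. Leaving out anti-PD1 replicates 1, 2 or 3 gave 104, 268 or 59 genes, and leaving out combination replicates 1, 3 or 4 gave 1548, 143 or 301.

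Against entrectinib alone, the comparison that asks what anti-PD1 added, the combination tumours had higher interferon, class I and cytotoxicity genes. Rtp4, an interferon-induced receptor transporter gene, rose from 16.2 ± 2.10 to 46.6 ± 7.80 CPM (log2 1.52 ± 0.18, adjusted p = 0.0007432), and Igtp, an immunity-related GTPase gene, from 79.9 ± 16.8 to 309.9 ± 49.2 CPM. Gzmb rose from 7.87 ± 2.64 to 40.7 ± 5.42 CPM (log2 2.37 ± 0.27, adjusted p = 0.0006696), Cxcl9 from 86.2 ± 24.6 to 349.7 ± 11.7 CPM (adjusted p = 0.001105), Pdcd1 from 1.51 ± 0.688 to 7.09 ± 2.27 CPM (adjusted p = 0.007768) and Cd274 from 26.1 ± 7.49 to 82.9 ± 30.7 CPM (adjusted p = 0.008049).

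Interferon alpha response genes rose in 27 of 28, and in 28 adjusted over the list alone (median 1.25, camera adjusted p = 9.814e-35, adjusted p = 0.06411 with an estimated correlation), including Oasl2 (log2 1.21) and Xaf1 (1.19). Interferon gamma response genes rose in 24 of 25, and 25 adjusted over the list alone (median 1.7, camera adjusted p = 3.287e-63), and MHC class I genes in 20 of 20 by either adjustment, adjusted over the list alone included (median 0.84, camera adjusted p = 2.674e-33), and both calls held with an estimated correlation (adjusted p = 0.03568 each). Cytotoxicity genes were higher in 14 of 17, and 16 adjusted over the list alone (median 2.18, camera adjusted p = 4.036e-20, adjusted p = 0.0598 with an estimated correlation), such as Gzma (2.42) and the death ligand gene Fasl (3.04). T cell markers were higher in 6 of 14, and in all 14 adjusted over the list alone. The median was 1.67 (camera adjusted p = 3.205e-09, adjusted p = 0.2704 with an estimated correlation). Checkpoint genes were higher in 8 of 13, and 11 adjusted over the list alone. The median was 1.31 (camera adjusted p = 1.79e-09, adjusted p = 0.06581 with an estimated correlation). Mast cell, eosinophil and basophil markers were higher in 4 of 12, and 6 adjusted over the list alone (median 1.33, camera adjusted p = 0.001068, adjusted p = 0.3515 with an estimated correlation), led by the mast cell proteases Cma1 (2.07) and Mcpt4 (2.04).

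Some stress and hypoxia genes fell. Immediate early and stress genes fell in 6 of 18, and in 9 adjusted over the list alone (median -0.49, camera adjusted p = 1.506e-05, adjusted p = 0.2783 with an estimated correlation), with Hspa1a at -2.53 on the log2 scale. Hypoxia response genes fell in 4 of 19, and 7 adjusted over the list alone (median -0.45, camera adjusted p = 2.485e-05, adjusted p = 0.4069 with an estimated correlation), among them Egln3, an oxygen sensor gene (-1.14), and Ddit4 (-1.01). Osr2 fell from 43.1 ± 7.19 to 7.45 ± 2.10 CPM (adjusted p = 0.0005545). Muscle genes were lower in 9 of 20, and in 13 adjusted over the list alone. The median was -2.98, the same with the 3 genes at 0 in the combination set to their bound (camera adjusted p = 1.929e-08, adjusted p = 0.2783 with an estimated correlation).

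Of 19983 genes, 1191 differed between combination and entrectinib tumours, 775 higher and 416 lower, with 4886 at an unadjusted p under 0.05. With combination replicates 1 and 2 only, chosen after seeing the data, 394 passed (336 higher, 58 lower, 337 shared with the 1191), among them 18 interferon gamma, 13 interferon alpha and 14 class I genes. The fit to replicates 3 and 4 only, chosen likewise, gave 3658 (1876 higher, 1782 lower), and DESeq2 2685. The count was 419, 724 or 528 without entrectinib replicates 1, 2 or 3, and 427 or 738 without combination replicates 3 or 4.

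The interaction asked whether the effect of entrectinib differed between tumours with and without anti-PD1. It too includes whatever set combination replicates 3 and 4 apart. Several of the genes that passed had similar means in the IgG, entrectinib and anti-PD1 tumours and another level in the combination. Ifi47 had means of 52.8, 48.7, 57.8 and 164 CPM in IgG, entrectinib, anti-PD1 and combination tumours (log2 interaction 1.62 ± 0.23, adjusted p = 0.03406). Thy1, a surface protein of T cells and fibroblasts (chromosome 9, 44043384 to 44048579), had 7.98, 7.03, 7.30 and 25.5 CPM (1.99 ± 0.29, adjusted p = 0.03406), and Ly6a, the Sca-1 antigen, 165.1, 157.1, 170.4 and 494 CPM (1.61 ± 0.25, adjusted p = 0.04883). Gpr171, a G protein-coupled receptor gene, had 3.49, 2.06, 3.71 and 10.7 CPM (2.28 ± 0.33), and Ube2l6, the conjugating enzyme for the ubiquitin-like ISG15, 59.0, 56.5, 61.2 and 114.4 CPM (0.97 ± 0.15). Osr2 went the other way, with 37.2, 43.1, 34.7 and 7.45 CPM (-2.43 ± 0.38, adjusted p = 0.04883), as did Mlph, melanophilin (chromosome 1, 90915085 to 90951142), with 11.4, 11.8, 14.6 and 6.86 CPM (-1.14 ± 0.16).

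As a group, 1 of 25 interferon gamma response genes passed the interaction test, and 22 adjusted over the list alone. The median was 1.5 (camera adjusted p = 2.381e-32, adjusted p = 0.1972 with an estimated correlation). For interferon alpha response genes these were 0 of 28 and 28 adjusted over the list alone (median 1.43, camera adjusted p = 8.294e-32, adjusted p = 0.1972 with an estimated correlation), for MHC class I 0 of 20 and 17 adjusted over the list alone (median 0.75, camera adjusted p = 1.533e-16, adjusted p = 0.1972 with an estimated correlation), and for cytotoxicity 0 of 17 and 12 adjusted over the list alone. The median was 1.88 (camera adjusted p = 2.422e-10, adjusted p = 0.4085 with an estimated correlation). Stat1 had an interaction of 1.25 ± 0.24 (adjusted p = 0.06746) and Gzmb of 2.01 ± 0.38 (adjusted p = 0.06255), so neither passed over all genes. Immediate early and stress genes had 0 of 18 past the threshold and 8 lower adjusted over the list alone. The median was -0.6 (camera adjusted p = 2.447e-05, adjusted p = 0.507 with an estimated correlation).

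By edgeR's test of the interaction, 9 of 19983 genes passed, 7 higher and 2 lower, and 3267 had an unadjusted p under 0.05. The count was 162 without combination replicate 1, 40 without IgG replicate 2 and 2 without IgG replicate 1. It was 1, a gene not among the 9, without entrectinib replicate 2 or combination replicate 4, and 0 without IgG replicate 3, entrectinib replicate 1 or 3, any of the 3 anti-PD1 replicates or combination replicate 2 or 3. With combination replicates 1 and 2 only, chosen after seeing the data, 1 gene passed and it was not among the 9. With combination replicates 3 and 4 only, also chosen after seeing the data, 2039 passed (1042 higher, 997 lower), and DESeq2 called 720 (532 higher, 188 lower).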

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

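The comparison of Y-linked genes between combination replicates 3 and 4 and the other tumours, the tests of these replicates alone and of a lower share of tumour cells, and the fits without 2 combination replicates were chosen only after the results they bear on were seen.

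The effect of entrectinib differed with and without anti-PD1 for 9 genes by the interaction test. The log2 interactions were 1.62 for Ifi47, 1.99 for Thy1, 2.28 for Gpr171, 1.61 for Ly6a, 0.97 for Ube2l6, -2.43 for Osr2 and -1.14 for Mlph, and 4.55 for Camk2n1, an inhibitor of CaM kinase II. The remaining one, 10.38 ± 1.47, was the unnamed gene model AL732309.1 (chromosome 2, 25244819 to 25246863), with means of 10.25, 0.2013, 0.4608 and 12.15 CPM in IgG, entrectinib, anti-PD1 and combination tumours. Camk2n1 stood at 1.354, 2.289, 4.189 and 6.059 CPM in combination replicates 1 to 4, and Ly6a at 389, 414.7, 637.3 and 535 CPM. In 2 of 100 splits of the 13 tumours, the real one included, as many genes passed the interaction test as the 9 of the real grouping. The highest other split gave 40. The splits moved tumours among all 4 treatments, so they broke up every difference between groups and not the interaction alone. They therefore cannot decide whether the 9 genes arose by chance. A split with several times as many genes points to a structure of the samples, and the split with 40 left combination replicates 1, 2 and 3 together under 1 label. What sets it apart was not tested.

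Among 76 quantities tested in the 4 combination tumours for a library far from the other 3, 2 passed the 95% critical value, and chance flags about 1 in 20. Fn1 was at 1584 CPM in replicate 4 against 1129, 1181 and 1122 CPM (gap over range 0.872), and Ltf at 8.706 CPM in replicate 2 against 0.3813, 0 and 0.6232 CPM (gap over range 0.928).

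Splits of the same libraries into groups of the same sizes bear on the other counts as well. For combination against IgG, 1 of 35 splits, the real one, gave as many as 770 genes and the highest other gave 5. For combination against entrectinib the real split was again the only 1 of 35 to reach its count (1191), and the highest other gave 290. Against anti-PD1 the real split was also the only 1 of 35 to reach 769, but the highest other gave 691. Each share is under 0.05 taken alone, and 1 of 35 is the smallest share that these splits can give. The shares were not adjusted for the number of comparisons, which all use the same combination tumours, so they do not exclude chance. Nor can they tell the treatment from whatever sets combination replicates 3 and 4 apart. Leaving out 1 replicate gave 138 to 975 genes against IgG, 419 to 1636 against entrectinib and 59 to 1548 against anti-PD1. The splits with 290 and 691 genes both put combination replicate 1 with the tumours given a single agent, which left replicates 2, 3 and 4 together. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. In the cells 1 of 10 splits reached 7141 and the highest other gave 0, and for entrectinib and for anti-PD1 against IgG all 10 of 10 reached the real count of 0, with highest others of 1 and 0.

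Combination replicates 3 and 4 lay apart from the other 11 tumours on the first principal component, although all 4 combination tumours carry the same treatment label. Depth as the whole cause is argued against by thinning every tumour library to the smallest total, which left 83.6% of the gap, and genes on the X and Y chromosomes by leaving out 667 of them, which left 97.6%. The 4 of 4 Y-linked genes measured were lower in both libraries than in each of the other 11 tumours, for example Ddx3y at 0.1961 and 0.2423 CPM against 6.468 to 13.97 CPM. Xist, at 867.2 and 826 CPM against 183 to 656.8 CPM, does not speak to the hosts, as the LL/2 cells themselves had 362.3 to 1828 CPM and at most 0.1258 CPM of Ddx3y. A candidate explanation is that these tumours grew in hosts of another sex than the others, perhaps as a separate experiment. Combination replicates 3 and 4 also differed in marks of library quality. Their rRNA gene share was 0.471 and 0.579% of counts, against 0.117 to 0.356% in the other 11 tumours. Genes with a count were 24429 and 24432, against 21973 to 23462. The labels give neither host sex nor batch, so what else differed between the pairs of combination tumours, and why, stays open. No tumour of another treatment shared the low Y-linked values. The comparisons with all 4 combination tumours therefore cannot separate treatment from this difference.

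Interferon gamma response genes rose in the combination against IgG with a median log2 change of 1.67. Combination replicates 3 and 4 alone do not carry it, since the median was 1.44 with replicates 1 and 2 only, and unequal depth is argued against by 1.66 after thinning. A lower share of tumour cells with all other cell types raised alike is argued against by their markers. The endothelial median was 0.3 (quartiles 0.05 to 0.55) and the fibroblast median 0.4 (-0.66 to 1.21), against quartiles of 1.42 to 1.95 for the interferon list. These markers cannot test a share lowered by immune cells alone, which stays open. Of genes with at least 5 CPM in a tumour group that were higher in the combination, 48.8% were under 1 CPM in shCTRL cells, against 10.1% of those lower. Genes low in the cells could meet the 5 CPM limit through the combination itself, so these shares do not bear on the source. The treatment itself may be the source, as a hypothesis from the same data. A higher share of T cells and a higher response per cell remain open, since bulk RNA does not separate them.

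The number of genes past the threshold in the cells, 7141, was weighed against technical trends. It was 7118 with every library thinned to the smallest total, 7991 with a trend on transcript length removed from each library (6612 shared with the 7141), and 7433 with a trend on GC content removed (6677 shared), with 4371 and 3916 of them higher against 3333 of the 7141. Depth, length and GC content are each argued against as the whole cause of the number, while the balance of directions changed with length and GC content. The hairpins may be the source, as a hypothesis. Ntrk1 had 0 counts in both groups, so the shCTRL cells showed no Ntrk1 RNA, up to 0.01443 CPM, that a hairpin could lower. These counts therefore give no support for an on-target effect through Ntrk1. Off-target effects of the hairpins, and differences between the cultures at harvest, stay open.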

How the results depend on the processing

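Combination replicates 1 and 2 only, 3 and 4 only, and total-count scaling without TMM were chosen after seeing the data. In the cells all alternatives stayed within 1.5 times of 7141 (5452 to 7595 without 1 replicate, 7821 with the replicate block). DESeq2 called more genes in the tumours, with 36 for entrectinib against IgG, 8 for anti-PD1 against IgG, 1861, 2484 and 2685 for the combination against IgG, anti-PD1 and entrectinib, and 720 for the interaction. Without the expression filter, which leaves more genes to adjust over, the combination gave 316 against anti-PD1 and 733 against entrectinib, and the interaction 0. The stricter filter gave 55 for the interaction and limma-voom 2. Fitting only the groups compared gave 682 against entrectinib. Combination replicates 1 and 2 only gave 360, 63, 394 and 1 for the combination against IgG, anti-PD1 and entrectinib and the interaction, and replicates 3 and 4 only 2262, 3588, 3658 and 2039. Each of these fits keeps 2 combination tumours, so a lower number of tumours does not account for the gap between them. The cause of that gap was not tested, nor that of the other shifts named here. Leaving out 1 replicate gave 0 to 3 genes for entrectinib, 0 to 1 for anti-PD1, 138 to 975, 59 to 1548 and 419 to 1636 for the combination in the same order, and 0 to 162 for the interaction. Of the genes called lower in the interaction, 1 was left with RLE scaling and 1 without TMM.

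Same-numbered tumours correlated at -0.072 to 0.17 in their deviations from group means (2 of 18 pairs over 0.1) and cells at -0.134 to 0.237 (2 of 3). For differently numbered libraries these were -0.141 to 0.076 in tumours (0 of 36) and -0.348 to 0.214 in cells (2 of 6). In the cells shNTRK replicate 2 went with shCTRL replicates 1 and 2 (0.2 and 0.237) and against shCTRL replicate 3 (-0.348). That shCTRL replicate went with shNTRK replicates 1 and 3 (0.214 and 0.18), and the remaining cell pairs were at -0.135 to -0.094. A block by number cannot model such a pattern, and its cause was not tested. The numbers were not taken to pair the samples. Both tumour pairs over 0.1 lay between entrectinib and anti-PD1 (0.17 and 0.118), so an effect shared by number stays open there. With the replicate block the combination gave 608, 187 and 680 genes against IgG, anti-PD1 and entrectinib and the interaction 1, which was not among the 9. Only the combination has a replicate 4, so the block also takes that tumour out of the comparisons. Leaving out that tumour without a block gave 655, 301 and 738 genes in the same order, and 1 for the interaction. Between the effects of entrectinib without and with anti-PD1, which share no library, agreement in calls could not be assessed because entrectinib against IgG called 0 genes, and log2 fold changes correlated across genes, which are not independent replicates, at -0.1 over 19983 genes and 0.098 over 13870 with a mean of at least 1 CPM.

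Among named genes, leaving out 1 replicate kept the direction and the side of the threshold in 4610 cases and ended the call in 793, the block in 625 and 101, and combination replicates 1 and 2 only in 285 and 174. With RLE scaling 740 kept both and 3 lost the call. Of the list results, 45 kept their side of the threshold with an estimated correlation and 123 lost the call, and with fry 82 kept it, 72 lost the call and 11 gained one. Depth limits genes near 0 such as Ntrk1.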

Other observations

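The gene groups and values of this part, and scaling without TMM, were selected after they were seen. Mitochondrially encoded genes differed in direction between shNTRK and shCTRL cells. Cytochrome b, mt-Cytb, fell from 3319 ± 569.4 to 403.7 ± 56.6 CPM, mt-Co2 by a log2 change of -2.54 and mt-Nd2 by -2.28, while mt-Co1, from the same polycistronic genome, rose by 0.69 ± 0.07. Nuclear genes of oxidative phosphorylation rose in 8 of 24, and 7 adjusted over the list alone (median 0.34, camera adjusted p = 0.02559, adjusted p = 0.7247 with an estimated correlation), a list call that ended without TMM (adjusted p = 0.05208). Histone genes rose in 6 of 12, and in 6 adjusted over the list alone (median 1.24, camera adjusted p = 0.001871, adjusted p = 0.2848 with an estimated correlation). MAPK feedback targets rose in 9 of 20 and fell in 4, with 9 and 4 adjusted over the list alone (median 0.66, camera adjusted p = 0.006932, adjusted p = 0.2083 with an estimated correlation).

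In the tumours some genes varied among the combination replicates. The maternally expressed RNA Meg3 was at 5.838, 2.881, 37.31 and 45.68 CPM in combination replicates 1 to 4 and at 0.9405 to 3.49 CPM in the other tumours. Ntrk2 had 249 and 320 counts and Ntrk3 70 and 131 in combination replicates 3 and 4, against at most 60 and 16 in any other tumour. Keratin RNA was seen in single tumours, with Krt5 at 19.4 CPM in anti-PD1 replicate 1, 5.55 CPM in IgG replicate 2 and at most 0.1422 CPM elsewhere. Of the genes with at least 5 CPM in a tumour group, 5.5% were under 1 CPM in shCTRL cells. That share was 48.8% (201 of 412) among genes higher in the combination than in IgG tumours and 10.1% (23 of 228) among those lower. The limit of 5 CPM could be met through the combination itself, which favours a high share among the genes higher there.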
